A study of Daphnia magna with 12 samples.

How the data were processed

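RNA from whole Daphnia magna was measured by mRNA sequencing in 12 libraries, 3 for each of 4 groups: medium alone, C2mimCl, C12mimCl and CholCl, the salts each at their EC20. Per the labels' protocols, 1440 neonates of brood 3, less than 10 h old, were assigned at random to 12 glass vessels with 120 animals in 500 mL each and kept for 48 h without food, and 90 active animals per vessel were pooled for RNA extraction. Replicates are therefore separate vessels of animals from the same cultures. Per the same labels' protocols, libraries were made with a stranded mRNA kit and sequenced as 150 bp paired-end reads. Because active animals were collected, the values describe animals that were still active after exposure.

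The deposited files hold whole-number counts of reads per gene for each library, not normalised, with 46334 gene rows and 5 summary rows. Per the submitters' processing notes, the tools used were Trimmomatic 0.39, STAR 2.7.3a and HTSeq. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Counts of overlapping or antisense genes, and of near-identical gene copies, are therefore uncertain. Reads with no unique position were 7.79% to 10% of each library and reads outside genes 5.25% to 10.1%; the widest half-width of a 95% Wilson interval on the latter and on the other per-library shares was 0.022 percentage points. Reads outside genes are here those that the counting tool assigned to no feature. With the annotation and strand setting unknown, they may include reads that lie within genes, such as intronic or antisense reads. Summary rows stayed out of library sizes and tests. The row of ambiguous reads held 0 in each library. Of the gene rows, 22708 were at 0 in each of the 12 libraries. None of the identifiers (0 matched) was found in the reference table of 28335 genes given for assembly ASM2063170v1.1, so no gene names were used, and the 42 gene lists fixed on product names could not be tested (0 were tested).

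Counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter (minimum count 10, minimum total 15), leaving 15847 genes with 99.9% of the reads in genes, and libraries were scaled with TMM factors. A quasi-likelihood model with robust estimation and 1 mean per group was fitted to the 12 libraries, which share 1 estimate of the spread. Each of 6 pairwise comparisons, and a joint test among the 4 groups, was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors were taken from the log2 fold change and its F statistic, with 95% intervals from the test's degrees of freedom. CPM values are normalised by the TMM factors. For a group with 0 reads a fold is a lower bound against a floor of 3 reads over the group, and for 1 to 3 reads a ratio with a counting interval is given. Such intervals and floors cover counting error only, since the reads carry no molecular identifiers.

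The design, the tests and the first set of other settings were fixed before the data were examined. The rule for named genes asked for product names and otherwise for the gene with the smallest p in each comparison. Without names it gave Dapma7bEVm013021, Dapma7bEVm015704 and Dapma7bEVm018393. The other genes named were chosen after their values were seen. They are the most abundant gene and genes with the largest changes among those with a mean of at least 2 CPM whose groups did not overlap. That first set held RLE and upper-quartile scaling, other count filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit of the 6 libraries compared, the replicate number as a block, an added 2-fold threshold, and leaving out each library in turn. Settings added after the data were seen were the share of reads outside genes as a covariate, library quality weights, TMM factors without the most abundant gene, and the other comparisons without C2mimCl replicate 1.

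The fit was tested on simulated data with known changes. For C2mimCl against control (15449 genes simulated and tested) it recovered 16 of 100 genes changed 2-fold and 65 of 100 changed 4-fold, with 2 unchanged genes called. For C12mimCl (15465 genes) it recovered 13 and 69 of 100 with 5 unchanged genes called, and for CholCl (15506 genes) 19 and 68 of 100 with 3. The 95% intervals held the simulated change for 96.5%, 98% and 96.5% of the changed genes. In this simulation, with 100 genes changed at each fold, most 2-fold changes were missed. C12mimCl and CholCl against control called far more genes than were changed here, which makes the adjusted threshold less strict. Their called genes had median changes of 2.02-fold and 2.33-fold, so the simulated recovery does not give their detection rate. Replicate libraries were compared by chi-square over genes, and the closest pair differed by 15.9 per degree of freedom, well above sampling noise, so each library was counted as 1 replicate. Overlap of calls was set beside that of independent lists and beside 20 simulated draws of unchanged groups against a shared simulated control group. In these draws every library, controls included, was drawn independently around the mean level of the controls. The number for independent lists takes every gene as equally likely to be called.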

Results

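Gene counts were analysed from whole bodies of the water flea Daphnia magna, a freshwater crustacean widely used in toxicity testing, after 48 h in medium alone or in medium with an organic chloride salt. C2mimCl (1-ethyl-3-methylimidazolium chloride) and C12mimCl share a methylimidazolium ring and chloride and differ in the alkyl chain, which is ethyl in the former and dodecyl in the latter. CholCl pairs chloride with cholinium, a quaternary ammonium ion that animals also use as a nutrient. Each salt was given at its EC20, the concentration that produces 20% of a measured effect. The endpoint and the molar concentrations are not given in the sources used here, so the salts are compared at matched effect levels and not at known concentrations. Each of the 4 groups had 3 libraries, and each library came from a pool of 90 animals taken from its own vessel. The libraries held 12502019 to 15539051 reads in genes and between 19493 and 20632 genes with at least 1 read. The files identify genes by number only and pair none with a name, so genes are described here as groups defined by their response and abundance, and a few by identifier.

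Of 15847 genes tested, 10374 (65.5%) differed among the groups in edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p below 0.05. The first principal component of log2 CPM (read counts scaled to a common library size) held 46% of the variance and placed the C12mimCl libraries between 115 and 132, with the other 9 libraries between -108 and 11.4. The second held 33.5% and placed the CholCl libraries between 77.8 and 131, with the other groups between -67.4 and -14.0. C2mimCl replicate 1 stood apart from its group at -12.2 on the first component. Across genes, which are not independent replicates, it correlated more with the control mean (r = 0.9358) than with the mean of the other C2mimCl libraries (r = 0.8955), whereas each of the other 11 libraries correlated best with its own group.

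**Figure D1:**
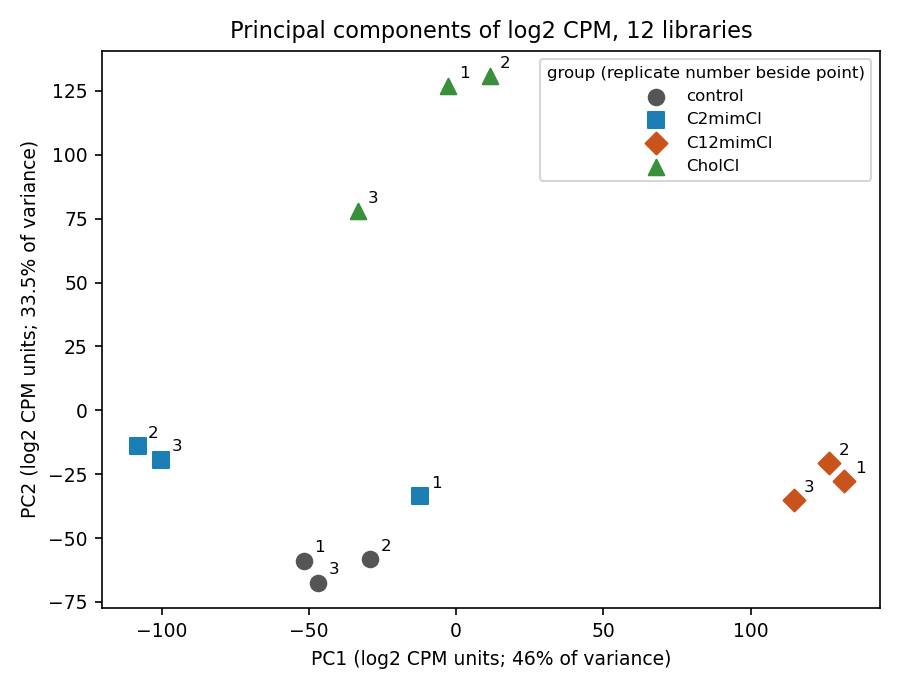
Each point is 1 of the 12 libraries, placed by its scores on the first (horizontal) and second (vertical) principal components of log2 CPM over the tested genes, with the percent of variance on each axis; colour and shape give the group and the digit the replicate. C12mimCl libraries lie at 115 to 132 on the first component, CholCl libraries at 77.8 to 131 on the second, and C2mimCl replicate 1 lies near the controls.

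The first comparison asked which transcripts differed after exposure to C2mimCl, the short-chain imidazolium salt. The genes called were few, with 123 higher and 104 lower than in controls, and the median change among them was 2.63-fold (4.73-fold without control replicate 2). Of the genes called, 7 rose and 20 fell by at least 8-fold. The large changes depended on the libraries used, with 2 rises and 7 falls without control replicate 1, 1 and 6 without control replicate 2, and 3 and 19 without control replicate 3. They numbered 10 and 228 without C2mimCl replicate 1, 8 and 7 without replicate 2, and 5 and 10 without replicate 3. Dapma7bEVm013021, the gene with the smallest p, fell from 24.6 ± 3.38 to 1.84 ± 0.384 CPM (SD, n = 3 each), a log2 fold change of -3.72 with SE 0.232 (edgeR's quasi-likelihood test, adjusted p = 8.8e-05). Dapma7bEVm007094 had 1 read in each C2mimCl library against 198, 189 and 118 reads in the controls, a ratio of 154 with a 95% counting interval of 52.8 to 748.

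Among genes with a mean of at least 2 CPM whose groups did not overlap, the largest rise after C2mimCl was that of Dapma7bEVm004588, which had 5413 reads in C2mimCl replicate 1 against 473 and 548 in the other C2mimCl libraries and 26 to 71 in the controls. Its log2 fold change was 5.24 with SE 0.96 (edgeR's quasi-likelihood test, adjusted p = 0.031), and it was 5.34, 5.47 and 4.97 without control replicates 1, 2 and 3 (adjusted p = 0.096, 0.12 and 0.089). Without C2mimCl replicate 1 it was 3.55 (adjusted p = 0.0059), below the 3.75 of Dapma7bEVm002925, so its size and rank rest on that library. C2mimCl genes were called at every level of abundance, from 0.131% of those with a mean under 1 CPM to 2.53% of those over 100 CPM. Falls were 45.8% of the calls with TMM scaling and 35.8% with upper-quartile scaling. The call count depended on every library of this comparison. It was 34, 23 and 91 without control replicates 1, 2 and 3, and 2445, 82 and 63 without C2mimCl replicates 1, 2 and 3. The balance of direction also turned on the libraries. Higher and lower genes numbered 932 and 1513, 60 and 22, and 41 and 22 without C2mimCl replicates 1, 2 and 3, and 16 and 18, 12 and 11, and 47 and 44 without control replicates 1, 2 and 3. Of the 227 genes, 19 were called in all 6 of these fits, and all 227 were still called, in the same direction, without C2mimCl replicate 1. Another test and other sample choices also moved it, with 1029 genes called by DESeq2's Wald test and 3 by edgeR's quasi-likelihood test on the 6 libraries compared. With the share of reads outside genes as a covariate, an alternative added later, 627 were called.

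The second comparison asked the same of C12mimCl, the long-chain imidazolium salt. Genes changed in both directions, with 2194 higher and 3407 lower than in controls (edgeR's quasi-likelihood test, adjusted p below 0.05), or 35.3% of genes tested. Large changes were almost wholly falls, since 755 genes fell and 5 rose by at least 8-fold. Such rises numbered 12 without control replicate 1 or 2, 83 without control replicate 3 (with 728 falls), 11 without C2mimCl replicate 1, and 8 and 10 without C12mimCl replicates 1 and 3. Those 755 genes together held 6.63% of gene reads in controls and 0.212% after C12mimCl, and their median level was 18.4 CPM in controls and 0.216 CPM after exposure. Dapma7bEVm015704, the gene with the smallest p, fell from 62.5 ± 6.14 to 0.711 ± 0.0886 CPM (SD, n = 3 each), a log2 fold change of -6.44 with SE 0.276 (edgeR's quasi-likelihood test, adjusted p = 3.1e-06).

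Under the same conditions of level and separation, Dapma7bEVm024815 had the largest rise after C12mimCl, a log2 fold change of 2.84 with SE 0.717 (edgeR's quasi-likelihood test, adjusted p = 0.013). Its log2 fold change was 2.57 without control replicate 1 and 2.15 without C12mimCl replicate 1, where the call was lost (adjusted p = 0.058 and 0.053), and 3.77 without control replicate 2. Its C12mimCl libraries had 353, 154 and 51 reads against 17, 52 and 10 in controls. Dapma7bEVm018652, at 2.81 with the 12 libraries, rose more than it without control replicate 2 (3.93) and without C12mimCl replicate 1 (2.41). The rank therefore rests on those libraries. The share of genes called grew with abundance, from 23.5% of those with a mean under 1 CPM to 45.2% of those over 100 CPM. The balance of smaller changes depended on scaling. Falls were 60.8% of the calls with TMM scaling and 40.2% with upper-quartile scaling, which moved the median log2 fold change of all genes from 0.03 to 0.25, whereas 700 genes still fell and 13 rose by at least 8-fold. The number called was 3422 without control replicate 1 and 3563 without C12mimCl replicate 1.

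The third comparison asked the same of CholCl. It gave 2515 genes higher and 3552 lower than in controls (edgeR's quasi-likelihood test, adjusted p below 0.05), or 38.3% of genes tested. Falls again made up most of the large changes, with 1038 genes lower and 42 higher by at least 8-fold, and 684 and 38 without CholCl replicate 1. The 1038 genes held 11.1% of gene reads in controls and 0.777% after CholCl, and their median level went from 23.8 to 1.33 CPM. Dapma7bEVm018393, the gene with the smallest p, fell from 38.3 ± 4.26 to 1.35 ± 0.242 CPM (SD, n = 3 each), a log2 fold change of -4.82 with SE 0.173 (edgeR's quasi-likelihood test, adjusted p = 4.8e-07).

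The largest rise after CholCl, under these conditions, was that of Dapma7bEVm029490, from 2.39 ± 0.53 to 146 ± 34.9 CPM (SD, n = 3 each), with a log2 fold change of 5.93 and SE 0.753 (edgeR's quasi-likelihood test, adjusted p = 0.00059). The same gene had a log2 fold change of 3.96 after C2mimCl (edgeR's quasi-likelihood test, adjusted p = 0.026) and -0.48 after C12mimCl (adjusted p = 0.62). After CholCl, Dapma7bEVm025960 rose by 5.68 on the log2 scale. It rose more than Dapma7bEVm029490 without control replicate 2 (6.045 against 5.842) and without CholCl replicate 3 (5.834 against 5.816), so the rank rests on those libraries. The most abundant gene of the data set, Dapma7bEVm011496, took 17.5% ± 3.01 of gene reads after CholCl and 7.55% ± 1.62 in controls (SD, n = 3 each). Its log2 fold change was 1.27 with SE 0.286 (edgeR's quasi-likelihood test, adjusted p = 0.0073). It took 10% ± 2.71 of gene reads after C2mimCl and 8.09% ± 0.488 after C12mimCl, neither called against controls (adjusted p = 0.4 and 0.69 in edgeR's quasi-likelihood test). Falls were 58.5% of calls with TMM scaling and 36.8% with upper-quartile scaling, which moved the median log2 fold change of all genes from -0.09 to 0.17, and with the latter 883 genes fell and 67 rose by at least 8-fold. The number called was 3572 without CholCl replicate 1.

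**Figure D2:**
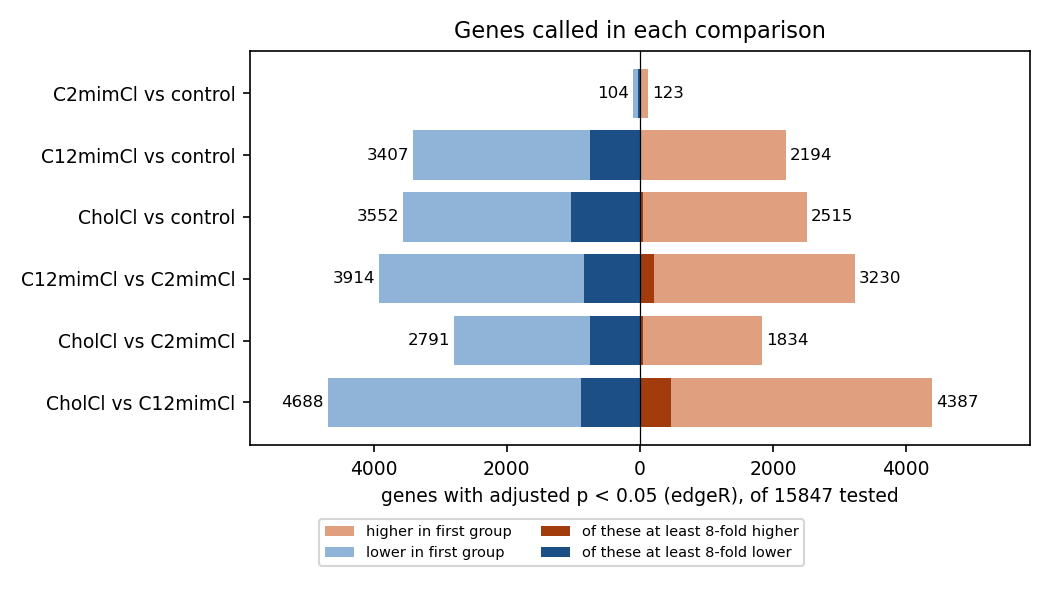
Bars give the number of genes called in each of the 6 comparisons (edgeR, adjusted p below 0.05), to the right those higher and to the left those lower in the group named first, with the darker part at least 8-fold. Against control, falls of at least 8-fold number 755 after C12mimCl and 1038 after CholCl, and rises of that size 5 and 42; the left share of each whole bar depends on the scaling, and is drawn for TMM.

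**Figure D3:**
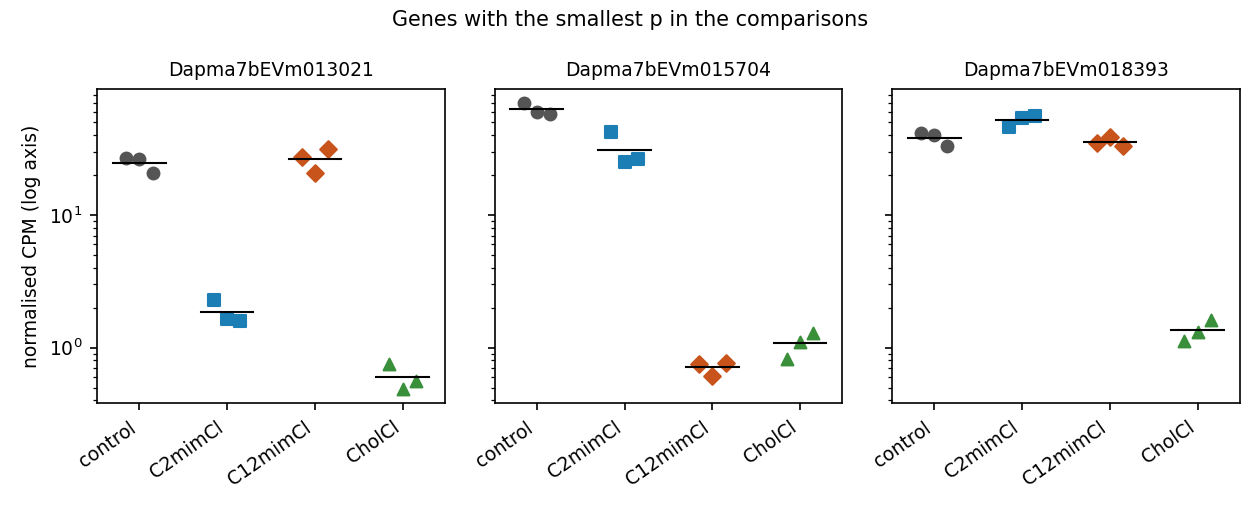
Points give the normalised CPM (log axis) of each library in the 4 groups, and black lines the group means, for the 3 genes with the smallest p in the comparisons. Dapma7bEVm013021 is low after C2mimCl (mean 1.84 CPM) and CholCl (0.6 CPM), Dapma7bEVm015704 after C12mimCl (0.711 CPM) and CholCl (1.07 CPM), and Dapma7bEVm018393 after CholCl (1.35 CPM).

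The responses to the salts were then set against each other over the genes called by both. C2mimCl and CholCl moved 157 genes in the same direction and 16 in opposite directions, where independent lists would share 42.8 and 44.1. C12mimCl and CholCl shared 957 lower genes against 764 for independent lists and 281 higher genes against 348, and 1032 went in opposite directions against 1030. Of genes at least 8-fold lower, 450 were common to C12mimCl and CholCl, where independent lists of 755 and 1038 would share 49.5. C2mimCl and C12mimCl moved 50 genes in the same direction and 44 in opposite directions, against 39.4 and 40.8. Of the 20 genes at least 8-fold lower after C2mimCl, 11 were also 8-fold lower after C12mimCl and 11 after CholCl, against 0.953 and 1.31 for independent lists. Without C2mimCl replicate 1 these were 23 and 136 of 228, against 11.2 and 15.7, and C2mimCl itself had 7 and 6 such falls without control replicates 1 and 2, and 7 and 10 without C2mimCl replicates 2 and 3. Against control, 14 genes were called higher and 18 lower after each of the 3 salts.

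Dapma7bEVm013021 and Dapma7bEVm007094 were low after both C2mimCl and CholCl. The former had a log2 fold change of -5.34 after CholCl (edgeR's quasi-likelihood test, adjusted p = 3.2e-06) and 0.11 after C12mimCl (adjusted p = 0.69). The latter had 0 reads in the CholCl libraries, at least 153-fold lower than in controls against a floor of 3 reads over the group, and rose after C12mimCl by 1.31 on the log2 scale (edgeR's quasi-likelihood test, adjusted p = 0.002). Dapma7bEVm015704 was low after both C12mimCl and CholCl, with a log2 fold change of -5.85 after CholCl (edgeR's quasi-likelihood test, adjusted p = 2.7e-06) and a 2-fold fall after C2mimCl (adjusted p = 0.044).

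All of these comparisons used the same 3 control libraries. Simulated unchanged groups against a shared simulated control group shared a mean of 0 calls but gave correlated fold changes (r = 0.498, 0.497 and 0.498 across genes for the pairs named next). These draws do not hold the particular traits of the real control libraries. The covariance of log2 fold changes was 0.356 for C2mimCl and CholCl against 0.0941 in the simulation, a difference of 0.262 (observed r = 0.381). It was 0.74 for C12mimCl and CholCl against 0.0935, a difference of 0.647 (r = 0.325), and -0.192 for C2mimCl and C12mimCl against 0.0938, a difference of -0.285 (r = -0.18). Without C2mimCl replicate 1 the covariance was 0.547 for C2mimCl and CholCl, 0.726 for C12mimCl and CholCl and -0.471 for C2mimCl and C12mimCl. The differences from the simulation were then 0.483, 0.661 and -0.535. Agreement in sign over all genes read otherwise. With the 12 libraries, fold changes had the same sign in 63.6% of genes for C2mimCl and CholCl, 47.3% for C12mimCl and CholCl and 46.8% for C2mimCl and C12mimCl. The simulation gave 66.6% for each. Without C2mimCl replicate 1 these shares were 68.6%, 47.2% and 40.9%, against 64.5%, 66.5% and 64.4% in the simulation. The controls were too few to be split, so part of the excess of shared calls may come from them. Leaving out C2mimCl replicate 1, an alternative chosen after the data were seen, gave 1709 same-direction and 253 opposite genes for C2mimCl and CholCl, against 623 and 575 for independent lists. For C2mimCl and C12mimCl it gave 246 and 1034, against 575 and 546, and for C12mimCl and CholCl 1816 and 2015, against 1860 and 1790. The last pair thus had more shared calls than independent lists with the 12 libraries and fewer without this library. Independent lists take every gene as equally likely to be called, but calls grew with abundance. From genes under 1 CPM to those over 100 CPM, the share called went from 23.5% to 45.2% after C12mimCl. After CholCl it went from 20.1% to 50.6%. Part of an excess over independent lists may come from that. Shared same-direction calls were 25, 19 and 68 for C2mimCl and CholCl without control replicates 1, 2 and 3. For C2mimCl and C12mimCl they were 5 and 7 without control replicates 1 and 2, and for C12mimCl and CholCl 668 without control replicate 1.

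**Figure D4:**
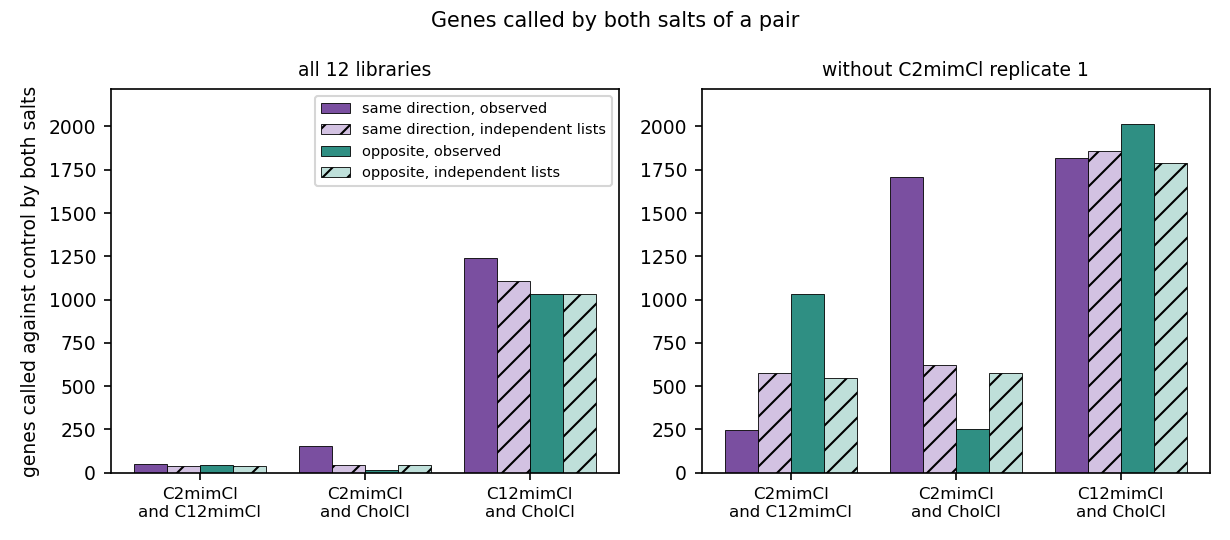
Bars give the number of genes called against control by both salts of a pair, in the same or in opposite directions, with hatched bars for the number that independent lists of the same lengths would share; the left panel uses the 12 libraries and the right panel leaves out C2mimCl replicate 1. C2mimCl and CholCl share 157 genes in the same direction and 16 in opposite directions with the 12 libraries.

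The imidazolium salts, which differ in alkyl chain length, were compared directly at their EC20 levels. After C12mimCl 3230 genes were higher and 3914 lower than after C2mimCl (edgeR's quasi-likelihood test, adjusted p below 0.05), with 218 and 840 of them at least 8-fold apart, and 729 and 955 without C2mimCl replicate 1. Dapma7bEVm015704 had the smallest p, with a log2 difference of -5.43 and SE 0.268 (edgeR's quasi-likelihood test, adjusted p = 8.1e-06). Of the 5734 genes called against control for either imidazolium salt, 4745 differed between them, and for 1454 the 95% interval of the difference lay within 2-fold. Over the genes tested, 5988 had an interval within 2-fold. Falls were 54.8% of the calls with TMM scaling and 42.7% with upper-quartile scaling, which moved the median log2 difference of all genes from 0.00246 to 0.17.

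CholCl was compared with each imidazolium salt in the same way. Against C2mimCl 1834 genes were higher and 2791 lower (edgeR's quasi-likelihood test, adjusted p below 0.05), and against C12mimCl 4387 were higher and 4688 lower. Dapma7bEVm018393 had the smallest p in both, with a log2 difference of -5.25 and SE 0.175 from C2mimCl (edgeR's quasi-likelihood test, adjusted p = 2.3e-07) and of -4.71 and SE 0.172 from C12mimCl (adjusted p = 5.9e-07). Of the 6121 genes called for CholCl or C2mimCl, 3638 differed between these salts and 1651 had an interval within 2-fold. For CholCl and C12mimCl, 7205 of 9398 differed and 2042 had such an interval. Falls were 60.3% of the calls against C2mimCl with TMM scaling and 37.8% with upper-quartile scaling, which moved the median of all genes from -0.0731 to 0.13. With the share of reads outside genes as a covariate, CholCl against C12mimCl gave 4180 genes instead of 9075, with 3321 in both. With it, C12mimCl against C2mimCl gave 4668 instead of 7144, with 3514 in both. This share was 5.25% to 5.83% after CholCl, 5.83% to 7.61% after C2mimCl and 8.11% to 10.1% after C12mimCl. It separates C12mimCl from both other salts, so the covariate also takes up the difference between them. The loss of calls cannot be told apart from that. CholCl against C2mimCl gave 2337 and 2974 genes without CholCl replicates 1 and 2, and 2254 with the 6 libraries compared.

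The 8-fold falls were followed across the other salts. Of the 755 genes that fell after C12mimCl, 541 were also lower and 40 higher after CholCl, and 16 were lower and 2 higher after C2mimCl. They held 7.98% of gene reads after C2mimCl and 1.45% after CholCl, with medians of 23.5 and 2.18 CPM against 18.4 CPM in controls. Between CholCl and C12mimCl themselves, 354 of the 755 were higher after CholCl and 2 lower. Of the 1038 genes that fell after CholCl, 502 were also lower and 17 higher after C12mimCl, and 30 were lower and 0 higher after C2mimCl. They held 9.13% of gene reads after C2mimCl and 8.33% after C12mimCl, but their median level was 18.2 CPM after C2mimCl and 3.36 CPM after C12mimCl, against 23.8 CPM in controls. The sets were not followed without C2mimCl replicate 1, on which the C2mimCl counts depend. Over the genes tested, those lower after both C2mimCl and CholCl numbered 82 with the 12 libraries and 1155 without it. Those lower after both C2mimCl and C12mimCl numbered 27 and 124.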

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

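The tests of genomic reads and of replicate numbers in this part were chosen only after the result was seen. Genes called against control in opposite directions by a pair of salts, and also different between those salts, numbered 44 for C2mimCl and C12mimCl, 16 for C2mimCl and CholCl, and 1032 for C12mimCl and CholCl (edgeR's quasi-likelihood test, adjusted p below 0.05 in each). Independent lists would give 40.8, 44.1 and 1030 opposite genes, and a difference between the salts follows from opposite calls, so it adds nothing to them. Of the 1032 genes, 421 were higher after C12mimCl and lower after CholCl, and 611 the reverse. Without C2mimCl replicate 1 the opposite-direction genes numbered 1034 for C2mimCl and C12mimCl, 253 for C2mimCl and CholCl, and 2015 for C12mimCl and CholCl, against 546, 575 and 1790 for independent lists.

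Reads outside genes, those assigned to no feature, are not used by the comparisons. They were 9.34% ± 1.08 of reads after C12mimCl and 7.53% ± 1.08 in controls (SD, n = 3 each, exact two-sided permutation p = 0.2, adjusted 0.2 over 6 comparisons, where 3 libraries against 3 cannot go below 0.1). In order of replicate number, they were 9.83%, 10.1% and 8.11% after C12mimCl and 7.87%, 8.39% and 6.32% in controls. C12mimCl was thus the higher for each number, which the unpaired test does not use. Reads outside genes were 6.53% ± 0.952 after C2mimCl and 5.53% ± 0.295 after CholCl. The difference was -3.81 points for CholCl against C12mimCl, -2 against controls and -1 against C2mimCl, and 2.81 for C12mimCl against C2mimCl (exact two-sided permutation p = 0.1, adjusted 0.15, in each of these). It was -0.996 points for C2mimCl against controls (exact permutation p = 0.2, adjusted 0.2). Reads with no unique position were 9.58% ± 0.536 after C12mimCl and 9.25% ± 0.196 in controls (exact two-sided permutation p = 0.4, adjusted 0.4). They were 8.72% ± 0.342 after C2mimCl and 7.91% ± 0.108 after CholCl, a difference of -1.34 points for CholCl against controls, -1.67 against C12mimCl and -0.81 against C2mimCl (exact permutation p = 0.1, adjusted 0.2, in each). For C2mimCl the difference was -0.531 points against controls, and C12mimCl differed from C2mimCl by 0.864 (exact permutation p = 0.2, adjusted 0.24, in both).

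Within groups, libraries differed along an axis shared between groups, scored in each group on the main direction of the other groups' deviations, and this axis followed the share of reads outside genes (Pearson r = -0.888, exact permutation p = 0.0054; Spearman rho = -0.909, exact permutation p = 0.0046; 1296 orders of libraries within groups; adjusted p = 0.011 over 2 relations, the other being depth with r = -0.645 and exact permutation p = 0.13). The first component of within-group deviations held 50.6% of their variance. With the scores kept as found from the 12 libraries, r was -0.902 without the 2 libraries farthest in that share (C12mimCl replicate 3 and control replicate 3). It was -0.915 over the libraries other than those of C2mimCl. The axis was not found anew without the left-out libraries, so it may still rest on those. After the gene counts of each library were thinned to the smallest total, r was -0.888, with the share of reads outside genes kept as it was. This argues against the number of reads itself as the cause. Thinning cannot exclude a difference between libraries that goes along with depth. In each of the 4 groups, the libraries with the most and the fewest reads outside genes were compared. At least 423 genes with a mean of at least 10 CPM were over 2-fold lower in the former. Genomic reads added to every gene cannot lower an abundant gene 2-fold, so they are not the whole difference between these libraries. The count cannot exclude them as a part, since libraries of a group were over 2-fold from their mates in 409 to 4328 of the tested genes. In each group replicate 3 scored above 0 and replicate 1 below 0, and between replicate numbers lay 49.4% of the variation of the axis, 58.3% of that of reads outside genes and 84.2% of that of depth (exact permutation p = 0.14, 0.1 and 0.0093, adjusted 0.14, 0.14 and 0.028), so the orders above may not be exchangeable. A difference that follows the number is argued against as the whole cause, since r was -0.765 with the number means removed. It was -0.74 to -0.818 without each group, with the scores kept from the 12 libraries. A difference that follows the number stays open as a part. RNA quality, developmental stage and handling of vessels also stay open. No biological explanation was tested, and the design names no difference between vessels of a group.

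Other splits of the libraries were counted for each comparison. For C2mimCl against control, 2 of the 10 splits of 6 libraries gave as many genes, the real one with 227 and the highest other with 2092. That other split set control replicates 1 and 2 and C2mimCl replicate 1 against the remaining libraries, and a count several times the real one points to a structure of the samples. In the other 5 comparisons the real split called 5601, 6067, 7144, 4625 and 9075 genes (C12mimCl and CholCl against control, C12mimCl and CholCl against C2mimCl, and CholCl against C12mimCl) and was the 1 split of 10 that reached that number, with 0 as the highest other. Because 10 splits cannot give a share under 0.1, they are too few to test chance. For the joint test of the 4 groups, 1 of 100 splits, the real one, gave as many as 10374 genes, with 3916 the highest other. That is the smallest share that 100 splits can give, and it argues against a random naming of the libraries. Splits that mix strongly unlike groups raise the spread within groups, so the count does not show that each group differs.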

How the results depend on the processing

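Settings were fixed beforehand unless named as added, and the cause of a change was not tested except where fewer libraries or a stricter threshold set it. RLE or upper-quartile scaling, either other filter and limma-voom kept each count of called genes within 1.5 times. DESeq2 called 1029 genes for C2mimCl against control, and shared same-direction calls became 201 for C2mimCl and C12mimCl and 684 for C2mimCl and CholCl. With only the 6 libraries compared, C2mimCl against control gave 3 and CholCl against C2mimCl 2254. A 2-fold threshold left 2844 (C12mimCl against control), 3617 (CholCl against control), 4367 (C12mimCl against C2mimCl), 2736 (CholCl against C2mimCl) and 5991 (CholCl against C12mimCl). Of the added alternatives, the share of reads outside genes as covariate gave 627 for C2mimCl against control, 4668 for C12mimCl against C2mimCl and 4180 for CholCl against C12mimCl. For C12mimCl and CholCl against control it kept 3602 of 5601 and 3268 of 6067 calls. The mean share itself differed between groups, so a lost call cannot be told from a treatment effect that the covariate takes up. Library quality weights (0.113 for C2mimCl replicate 1, 0.304 for control replicate 3) gave 4817, 8738 and 9124 for C2mimCl, C12mimCl and CholCl against control and 7052 for CholCl against C2mimCl.

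Leaving out 1 library at a time gave 23 to 2445 genes for C2mimCl against control (without control replicate 2 and without C2mimCl replicate 1), 3422 to 7434 for C12mimCl (control replicate 1, C2mimCl replicate 1), 3572 to 7949 for CholCl (CholCl replicate 1, C2mimCl replicate 1) and 2337 to 4447 for CholCl against C2mimCl (CholCl replicate 1, C2mimCl replicate 2). Over fits without each control and without C2mimCl replicate 1, the omissions run for them, shared same-direction calls ranged from 5 to 246 (C2mimCl and C12mimCl), 19 to 1709 (C2mimCl and CholCl) and 668 to 1816 (C12mimCl and CholCl). The log2 fold change of Dapma7bEVm011496 after C12mimCl, not called (0.16), was -0.0304 without control replicate 1 (adjusted p = 0.95) and up to 0.32. Of 173 alternative values for named genes, 161 kept direction and call, 11 lost the call, 0 gained one and 1 reversed.

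The replicate number as a replicate block gave 208 genes for C2mimCl against control (87 higher, 121 lower) and 33 shared calls for C2mimCl and C12mimCl, and kept every other count of calls within 1.5 times. It gave Dapma7bEVm004588 a log2 fold change of 4.81 after C2mimCl (5.24 without it) with adjusted p = 0.059. Same-numbered libraries correlated over 0.1 in 11 of 18 pairs (-0.406 to 0.426), among them all 6 pairs of replicate 3 (0.152 or more), and 4 of 12 libraries correlated best with their own number, so the numbers were not taken to pair libraries, although a difference that follows them in part stays open. Gene list tests were not run, since no identifier matched a name.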

Other observations

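The tests of a swapped label, of a wrong label and of variation between vessels in this part were chosen only after the result was seen. Called genes fell into opposed as well as shared responses. Among genes with no call for C2mimCl against control, 586 were lower after C12mimCl and higher after CholCl, 406 were higher after C12mimCl and lower after CholCl, and 935 and 266 were lower and higher after both. After CholCl, 20.1% of genes with a mean under 1 CPM and 50.6% of those over 100 CPM were called (edgeR's quasi-likelihood test).

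C2mimCl replicate 1 stood apart from the other C2mimCl libraries, with 4328 genes over 2-fold from their mean against at most 1822 in a library of the other groups. After thinning to the smallest total these numbers were 4300 and 1807, which argues against the number of reads itself. A mixture with material of other groups and an untreated control like the other 3 under a wrong label are argued against, because 119 genes of at least 10 CPM lay over 2-fold outside the range of the other 11 libraries, against 0 to 40 in the 9 libraries of the other groups and at most 9 in a control. A swap with control replicate 3 is argued against, because that library's median position between the other controls (0) and the other C2mimCl libraries (1) was 0.402 (quartiles 0.0925 and 0.724), where held-out C12mimCl and CholCl libraries lay at 0.892 to 1.09, although 1545 of its 3692 genes lay nearer to C2mimCl, C2mimCl replicate 1 lay at 0.0991 and exchanging these 2 libraries gave 2092 calls against 227. The median position of C2mimCl replicate 1 was near the controls at 0.153 over 601 genes, and of 200, 167 and 269 genes changed at least 8-fold, called without it and 1 control, it lay on the C2mimCl side of the other controls by over 4-fold for 22, 22 and 43 (1, 1 and 29 for the left-out control) and by over 2-fold for 41, 33 and 94 (13, 2 and 117), so control replicate 3 went further at 2-fold. A sample from outside the series, an untreated vessel in an unlike state, a weaker or different response to the salt and a difference between vessels stay open as untested.

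Falls of at least 8-fold outnumbered rises of that size after C12mimCl (755 and 5, with rises at 8 to 12 without control replicate 1 or 2, C2mimCl replicate 1 or C12mimCl replicate 1 or 3, and 728 and 83 without control replicate 3) and CholCl (1038 and 42, or 684 and 38 without CholCl replicate 1). The choice among 4 scalings is argued against, since falls were at least 53.8 times (C12mimCl) and 13.2 times (CholCl) the rises under each. Across them the median log2 fold change of all genes ran only from 0.031 to 0.248 (C12mimCl) and from -0.0929 to 0.167 (CholCl). A larger shift common to all genes was therefore not tested. Variation between vessels alone is argued against for C12mimCl. Of the falls found without 1 library, that library showed at least 80.5% by over 4-fold beyond the 3 libraries of the other group. For CholCl this was 71.7% or more, except for CholCl replicate 3, which showed 593 of 1178 (50.3%). Such variation is therefore argued against less clearly for CholCl. The genes also varied more between untreated vessels, with a median SD between controls of 0.573 log2 units for the C12mimCl set and 0.617 for the CholCl set, against 0.263 and 0.247 in sets matched on control level, at percentile 100 of 10000 such sets in both. Control replicate 3 had 1822 genes over 2-fold from the mean of the other controls, against 627 and 904 for control replicates 1 and 2. The SD was not found without it, so it may rest on that library. As a hypothesis, exposure may lower most strongly some genes that also vary between vessels.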
